A study of Mus musculus with 12 samples.

How the data were processed

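Total RNA from the hearts of 12 male C57BL/6J mice was hybridized by the authors to Clariom D mouse arrays from Affymetrix, 1 array per heart, after biotin labelling of 250 ng of RNA. Per the labels, the mice were 10 weeks old, and hearts were taken 2 weeks after sham surgery or transverse aortic constriction (TAC). Genotype (wild type or Adam12 knockout) and surgery gave 4 groups of 3 biological replicates. The deposited value table held log2 signals for 65527 probe sets on every array. Per the submitters' processing notes these came from Affymetrix Expression Console, whose version was not stated, and the normalization and summarization methods were not given in the sources used here. That the values were log2 signals was settled from the table itself, whose values ran from 1.27 to 19.93, the latter a linear signal of 999966.3.

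Control probe sets (6732) were left out. Of the other 58795 probe sets, 27268 carried 1 gene symbol, 1932 carried several and 29595 carried none in the annotation used here. Genes were tested as the probe set with the highest mean signal among those with exactly 1 symbol, which gave 26989 genes, of which 198 had more than 1 probe set. No filter on dim genes was applied. The probe set of Adam12 carries another symbol as well and was therefore read on its own, in a fit of all probe sets.

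Differences between groups were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, default empirical Bayes moderation (prior degrees of freedom 3.29, residual degrees of freedom 8), 2-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Errors beside differences of single genes are the standard errors of limma, and errors beside levels are standard deviations over 3 arrays. The comparisons were TAC against sham in each genotype, knockout against wild type after each surgery, the difference between the TAC responses of the genotypes (the interaction), and both effects averaged over the other factor. A TAC response score was computed per array from the genes called in the averaged TAC comparison, which weighs the genotypes alike. It was the mean of the 2021 genes that rose minus the mean of the 1652 genes that fell. The choice of genes also used the spread within the 4 real groups, and it was not repeated for permuted labels. The score was compared with 2-sided exact permutation tests, over 20 assignments for knockout against wild type and over 400 for the interaction.

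The comparisons, the tests, the lists and the rule for named genes were chosen before the data were examined. By that rule Adam12 was given in every sample. Per comparison, up to 12 genes with the largest rise and 12 with the largest fall were named among called genes whose groups did not overlap. Where fewer than 5 passed in a direction, the 5 with the smallest p were given as values. Up to 4 members with the smallest p were taken from each list described, together with a fixed set of heart genes such as Nppa, Myh7 and Col1a1. Predicted genes, small RNAs and receptors of smell were passed over, and any gene named outside the rule is said to have been chosen after its values were seen.

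The 34 gene lists covered heart muscle programs, matrix, signalling, metabolism, stress responses and markers of the cell types a heart sample could hold, together with neighbours of Adam12 on mouse chromosome 7 and sex-linked genes. They held 616 entries, of which 504 were measured on a probe set of their own, 17 shared a probe set with another symbol and 95 were not analysed here. Lists were tested with camera at its preset correlation, with Benjamini-Hochberg adjustment over the 34 lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way and does not compare them with other genes. No list passed in any comparison with an estimated correlation. By fry 17 lists passed for TAC in the knockout, 21 for TAC averaged over genotypes, 8 for genotype after TAC and 0 in the other comparisons.

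The procedure was tested on simulated data with independent noise, in which 50 genes were changed at each fold. For TAC in the knockout it recovered 41 genes at a fold of 1.5, 46 at 2, 50 at 4 and 49 at 8, with 12 unchanged genes called. For knockout against wild type after TAC it recovered 37, 46, 50 and 49 at the same folds, with 10 unchanged genes called. For the interaction it recovered 13, 40, 50 and 48, with 8 unchanged genes called. For TAC in the wild type and for genotype after sham nothing was changed and 0 genes were called. Both lists shifted by 0.5 were called in each comparison that held them and 0 others were. The simulated noise was independent, while correlations estimated within the real lists reached 0.798. The 0 other lists therefore do not show how often camera calls real lists by chance. Camera was also run with the real arrays divided otherwise between groups. It then called a median of 10 lists for TAC in wild type, 11 for TAC in knockout, 9 for genotype after TAC, 4 for genotype after sham and 8 for the interaction.

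The alternatives tried were renewed quantile normalization, centring of each array on its median, the mean of all probe sets of a gene, leaving out dim genes, testing all probe sets, array weights, a trended and robust variance model, the replicate number as a block, only the arrays of the groups compared, an added fold threshold of 1.5 and leaving out each array in turn. The array median as a covariate and the level of Myl7, an atrial myosin light chain, as a covariate were chosen after seeing the data. For arrays the number of samples limits the precision. The files gave no scan or collection dates, so no batch could be tested. The top of the table looked like a ceiling, which was not tested. Nppa lay within 0.3 of it on the 3 knockout TAC arrays, so its differences there may be compressed.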

Results

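Heart RNA was measured on 12 arrays, 3 for each combination of genotype (wild type or Adam12 knockout) and surgery (sham or TAC). TAC narrows the aortic arch and so raises the pressure against which the left ventricle pumps. ADAM12 is a membrane-anchored metalloprotease of the ADAM family. The series asks how hearts without it change their gene expression under this load. The arrays had like signal, with medians over all probe sets from 5.06 to 5.19 on the log2 scale and medians of background probe sets from 2.96 to 3.17.

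Adam12 was read on a dim probe set shared with 5830403F22Rik, brighter than 37.8% of probe sets. Its level was 4.54 ± 0.07 in wild type sham hearts, 4.70 ± 0.12 in wild type TAC hearts, 4.35 ± 0.04 in knockout sham hearts and 4.33 ± 0.08 in knockout TAC hearts (SD, n = 3 each). In wild type sham replicates 1 to 3 it read 4.54, 4.46 and 4.61, and in wild type TAC replicates 4.56, 4.73 and 4.80. In knockout sham replicates it read 4.33, 4.40 and 4.32, and in knockout TAC replicates 4.25, 4.40 and 4.36. All 6 knockout arrays lay below all 6 wild type arrays, by -0.28 ± 0.06 averaged over surgery (exact permutation p = 0.005, 400 assignments, 2-sided). In the limma fit of all probe sets the difference did not pass, at adjusted p = 0.434, and its TAC difference in wild type hearts was 0.16 ± 0.08 at adjusted p = 0.564. Which part of the gene the probes cover was not known here.

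In wild type hearts TAC raised Acta1, the skeletal actin of the fetal heart program, by 2.35 ± 0.37, from 14.04 ± 0.40 to 16.38 ± 0.69 (SD, n = 3). Emp1, a membrane protein, rose by 1.70 ± 0.28. Cd72, Cd34 and Cd52, surface proteins of blood or vessel cells, rose by 0.74, 0.70 and 0.58, and the guidance receptors Unc5b and Nrp2 by 0.78 each. Txnip, which restrains glucose uptake, fell by 2.39 ± 0.27, the largest fall among called genes. The acyl-CoA thioesterase Acot1 fell by 1.35 ± 0.18 and the fatty acid transporter Slc27a1 by 0.95 ± 0.15. Corin, the protease that activates atrial natriuretic peptide, fell by 1.05, and Nt5e, which makes adenosine, by 1.10. The other named genes were Nav3, Psmb10, Sh3bgr, Ephx1 and Stim2, which rose by 0.45 to 0.92, and Klhl38, Maob, Rnf122, Arhgap20, Zc3h6, Fam214a and Phkg1, which fell by 0.88 to 1.44. The collagens and matrix list had a mean difference of 1.08 with all 31 members positive, but 0 of 31 passed over all genes and 25 were higher when adjusted over the list alone. Postn, a matrix protein of activated fibroblasts, differed by 2.56 ± 0.45 at adjusted p = 0.0604, and Col1a1 by 1.32 ± 0.42 at adjusted p = 0.22. Without wild type TAC replicate 2 the mean was 0.595. The list was called higher by camera (adjusted p = 6.94e-18, adjusted p = 0.402 with an estimated correlation). Of 21 fatty acid oxidation genes 1 fell over all genes and 16 fell when adjusted over the list alone, with a mean of -0.50 (camera adjusted p = 3.09e-17, adjusted p = 0.258 with an estimated correlation). Of 14 fetal and hypertrophy genes 1 rose over all genes and 5 adjusted over the list alone, with a mean of 0.61 (camera adjusted p = 4.16e-05, adjusted p = 0.402 with an estimated correlation). Fibroblast markers had a mean of 0.52, or 0.281 without wild type TAC replicate 2, with 0 of 14 over all genes and 6 higher adjusted over the list alone (camera adjusted p = 0.000413, adjusted p = 0.512 with an estimated correlation).

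In all, 18 genes rose and 30 fell in wild type hearts at an adjusted p under 0.05 by limma, and 3330 had an unadjusted p under 0.05 against 1349 expected by chance. The groups did not overlap for 16.1% of genes, where chance gives 10%. The count rested on single arrays: it was 0 without wild type sham replicate 1 or 3, wild type TAC replicate 2, knockout sham replicate 2 or knockout TAC replicate 3, and 264 without wild type TAC replicate 3. It was 15 without wild type sham replicate 2, 6 without wild type TAC replicate 1, 12 without knockout sham replicate 1, 1 without knockout sham replicate 3 and 27 without knockout TAC replicate 1. It was 0 in a fit of only the 6 wild type arrays, 0 with Myl7 as a covariate, 74 after quantile normalization, 167 without dim genes and 352 with array weights.

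In knockout hearts TAC changed 3444 genes, 1910 higher and 1534 lower. Genes of the extracellular matrix were prominent among the largest rises: Cilp by 4.71 ± 0.67, Thbs4 by 4.60 ± 0.65, Postn by 4.57 ± 0.45, fibronectin (Fn1) by 4.07 ± 0.46, and Comp, Col3a1, Ltbp2, Col1a1, Col1a2 and Col12a1 by 3.22 to 4.02. Serpina3n, a secreted protease inhibitor, rose by 4.50 and Meox1, a transcription factor of activated fibroblasts, by 3.23. Of 31 collagen and matrix genes 29 rose, and all 31 when adjusted over the list alone, with a mean of 2.70 (camera adjusted p = 6.84e-35, adjusted p = 0.2 with an estimated correlation). Col1a1 went from 9.85 ± 0.10 to 13.25 ± 0.26 (SD, n = 3).

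The fetal and hypertrophy genes rose in the knockout as well, 10 of 14 up and 2 down over all genes and 11 up and 2 down adjusted over the list alone. Acta1 rose by 2.97 ± 0.37, Nppb, which encodes the B-type natriuretic peptide, by 2.50 ± 0.32, Myh7, the slow myosin heavy chain, by 1.77 ± 0.25 and Nmrk2 by 1.60 ± 0.15. The list's adjusted p was 1.63e-08 by camera, with adjusted p = 0.2 with an estimated correlation. Nppa differed by 1.39 ± 0.46 at adjusted p = 0.0761, with knockout TAC values near the top of the table, and Myh6, Atp2a2 and Pdk4 did not pass either. Among adult contractile and calcium handling genes 7 of 14 fell and 2 rose over all genes, 9 and 2 adjusted over the list alone, with Ryr2, the calcium release channel, at -0.48 ± 0.07 and Tnni3 at -0.58 ± 0.08 (camera adjusted p = 0.00121, adjusted p = 0.254 with an estimated correlation).

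Genes of energy metabolism fell in the knockout. Of 21 fatty acid oxidation genes 18 fell over all genes and 20 adjusted over the list alone, Slc27a1 by 1.53 ± 0.15 and Hadh by 0.83 ± 0.10 among them (camera adjusted p = 5.62e-18, adjusted p = 0.2 with an estimated correlation). Of 21 oxidative phosphorylation genes 18 fell over all genes and 21 adjusted over the list alone, with a mean of -0.48 (camera adjusted p = 6.22e-15, adjusted p = 0.2 with an estimated correlation). The mitochondrial thioesterase Acot2 fell by 2.29 ± 0.23, Acot1 by 2.02 ± 0.18 and the carboxylesterase Ces1d fell by 2.25 ± 0.26. Timp4, Kcnj3, Cabcoco1, Mylk4, Zbtb16, Fbp2, Lgals4, Gpr22 and Adhfe1 fell by 1.74 to 2.21.

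Part of the lists of growth factor signalling and adhesion rose in the knockout. Of 19 TGF-beta and BMP genes 9 rose and 1 fell over all genes, 10 and 3 adjusted over the list alone, with Tgfb2 at 1.98 ± 0.28, Tgfbr1 at 1.05 ± 0.12 and Fstl1 at 2.71 ± 0.30 (camera adjusted p = 4.5e-06, adjusted p = 0.213 with an estimated correlation). Of 19 integrin genes 12 rose and 2 fell over all genes, 12 and 3 adjusted over the list alone, with Itga5 at 1.16 ± 0.14 and Itgb1 at 0.54 ± 0.08 (camera adjusted p = 1.15e-06, adjusted p = 0.2 with an estimated correlation). Of 12 matrix proteases and inhibitors 9 rose and 1 fell, and as many adjusted over the list alone, with Mmp14 at 2.33 ± 0.35 and Mmp3 at 1.73 ± 0.20 (camera adjusted p = 1.86e-07, adjusted p = 0.2 with an estimated correlation). In the ADAM family 4 of 10 rose and 1 fell, and as many adjusted over the list alone, with Adam9 at 0.78 ± 0.09, Adam10 at 0.62 ± 0.07 and Adam15 at 0.54 ± 0.07 (camera adjusted p = 0.0225, adjusted p = 0.213 with an estimated correlation). In the IGF axis 5 of 12 rose, and as many adjusted over the list alone, with Igf1 at 1.33 ± 0.20 and Igfbp5 at 0.73 ± 0.19 (camera adjusted p = 0.00305, adjusted p = 0.213 with an estimated correlation).

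Markers of other cells moved in the knockout too. Of 14 fibroblast markers 11 rose over all genes and 12 adjusted over the list alone, with a mean of 1.26 (camera adjusted p = 2.2e-09, adjusted p = 0.213 with an estimated correlation). The matrix list holds 4 of these markers, and of the other 10 markers 8 rose. Of 15 macrophage and monocyte markers 10 rose, and as many adjusted over the list alone, with Ccr2 at 2.24 ± 0.29 and Cd68 at 0.96 ± 0.16 (camera adjusted p = 8.58e-08, adjusted p = 0.213 with an estimated correlation). Of 18 proliferation genes 13 rose over all genes, and 16 rose and 1 fell adjusted over the list alone, with Ccna2 at 1.27 ± 0.19 (camera adjusted p = 4.88e-11, adjusted p = 0.23 with an estimated correlation). Of 14 interferon response genes 7 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 8.58e-08, adjusted p = 0.23 with an estimated correlation). Endothelial markers had a mean of 0.11 and were not called (camera adjusted p = 0.0821).

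In the knockout 32.3% of genes did not overlap between surgeries, where chance gives 10%, and 1518 genes passed with an added fold of at least 1.5. Leaving out knockout TAC replicate 2 gave 2098 genes and leaving out knockout sham replicate 3 gave 2206. Zbtb16, Gpr22 and Igfbp5 lost their calls without knockout sham replicate 2 or 3 or knockout TAC replicate 2, among others.

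**Figure D1:**
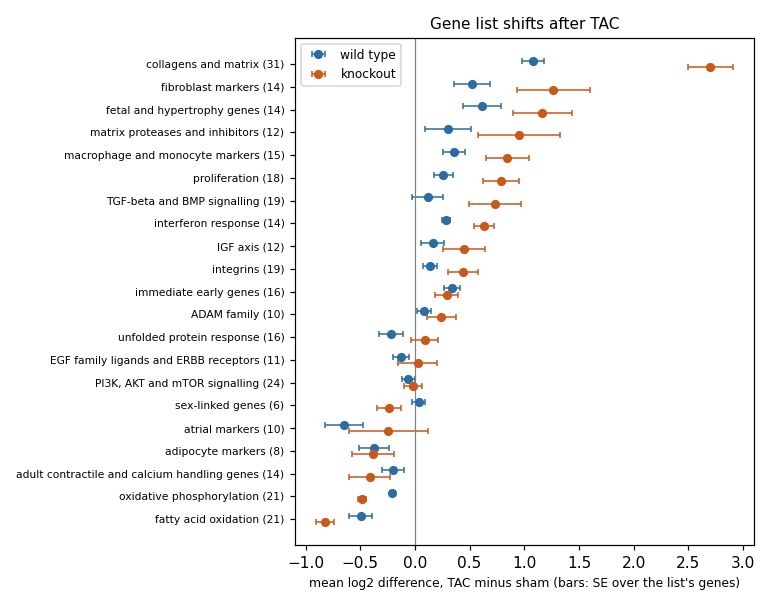
Mean log2 difference between TAC and sham (x axis) for gene lists that camera called at its preset correlation in at least 1 genotype (y axis, measured genes in parentheses), in wild type (blue) and knockout (orange) hearts, with bars for the standard error over the list's genes. The matrix list lies at 1.08 in wild type hearts (0.595 without TAC replicate 2) and 2.70 in knockout hearts, and the fatty acid oxidation list at -0.50 and -0.82.

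Most genes called in the knockout had the same sign in wild type hearts, on separate arrays: of the 3404 genes called in the knockout alone, 3171 (93.2%) did, and 1481 had an unadjusted p under 0.05 there. Averaged over genotypes, TAC changed 3673 genes, 2021 higher and 1652 lower, led by Postn (3.56 ± 0.32), Cilp (3.53 ± 0.48) and Thbs4 (3.39 ± 0.46) upward and by Zbtb16 (-2.06 ± 0.34) and Timp4 (-1.84 ± 0.31) downward. Of 31 collagen and matrix genes 29 rose, and 31 adjusted over the list alone (camera adjusted p = 1.52e-31, adjusted p = 0.249 with an estimated correlation), while 20 of 21 fatty acid oxidation genes fell, and as many adjusted over the list alone (camera adjusted p = 3.77e-20, adjusted p = 0.249 with an estimated correlation). Of the 3673 genes, 3263 (88.8%) had a larger effect in the knockout, with a median ratio of 2.00. Of the 18 genes that rose in wild type hearts 17 also rose in the knockout, where 1.3 would be shared by independent calls, and of the 30 that fell 23 also fell, where 1.7 would be shared. Both tests used the same estimate of spread for each gene, so their calls are not independent and these baselines are too low. Across genes, which are not independent replicates, the TAC effects of the genotypes had r = 0.57. With an added fold of at least 1.5 the averaged count was 818.

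The TAC response score rose more in knockout than in wild type hearts. Its mean was -1.22 ± 0.03 in wild type sham, -0.59 ± 0.21 in wild type TAC, -1.24 ± 0.07 in knockout sham and -0.02 ± 0.16 in knockout TAC hearts (SD, n = 3 each). The score thus rose by 0.63 in wild type and by 1.22 in knockout hearts, a difference of 0.59 (exact permutation p = 0.03, 400 assignments, 2-sided). Knockout TAC arrays lay above wild type TAC arrays by 0.57 (exact permutation p = 0.1, the smallest that 20 assignments allow), and sham arrays differed by -0.02 (exact permutation p = 0.6). The p of the interaction lay below 0.1 only through this small sham difference, so it adds no evidence from the TAC arrays themselves. The genes of the score were chosen with the spread within the real groups and not anew for each assignment. The permutation p may therefore be too small. Leaving out single arrays gave interactions from 0.47 to 0.79 with exact permutation p from 0.005 to 0.09. The p was over 0.05 without wild type sham replicate 1 or 2, knockout sham replicate 3 or knockout TAC replicate 1 or 2.

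**Figure D2:**
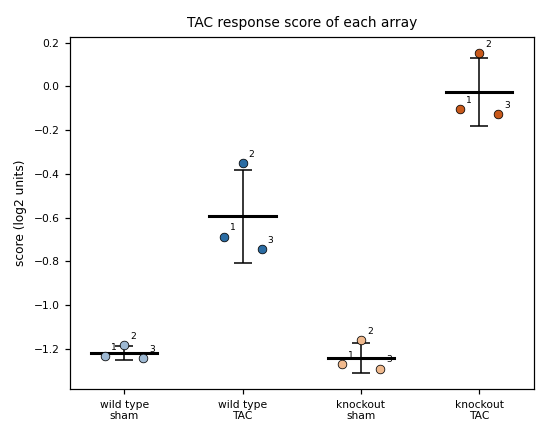
TAC response score of each array (y axis, log2 units) by group (x axis), with the mean (line), SD (bar) and replicate number. The group means are -1.22, -0.59, -1.24 and -0.02, so the arrays of knockout TAC hearts lie highest.

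After TAC, 3 genes were higher in knockout than in wild type hearts and 0 were lower. Mmp3, the protease stromelysin, was higher by 1.67 ± 0.20, Ccn5, a matricellular protein, by 1.18 ± 0.15 and Fam180a by 0.84 ± 0.09, each at adjusted p = 0.044. Mmp3 stood at 6.77 ± 0.31 in wild type and 8.44 ± 0.16 in knockout TAC hearts, Ccn5 at 7.12 ± 0.27 and 8.30 ± 0.26 and Fam180a, dim in the other groups, at 4.53 ± 0.08 and 5.36 ± 0.08 (SD, n = 3). Next came genes at adjusted p = 0.0592 that did not pass: Anxa2 at 1.00 ± 0.14 and Nmrk2 at 1.10 ± 0.15 upward, and Prxl2a, Lmod3, Dgat2, Asb15 and Dbt at -0.99 to -0.54 downward. Of 31 collagen and matrix genes 0 passed over all genes and 29 were higher adjusted over the list alone, with a mean of 1.63, Col3a1 at 2.21 ± 0.38 and Tnc at 1.84 ± 0.28 (camera adjusted p = 8.84e-37, adjusted p = 0.154 with an estimated correlation).

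Other lists called between the TAC groups had 1 member at most past the threshold over all genes. Of 12 matrix proteases and inhibitors 1 was higher over all genes and 9 adjusted over the list alone (camera adjusted p = 2.21e-09, adjusted p = 0.149 with an estimated correlation). Integrins had 0 of 19 over all genes and 11 higher and 1 lower adjusted over the list alone, with Itga5 at 0.93 ± 0.14 and Itgb6 at -0.69 ± 0.14 (camera adjusted p = 9.25e-09, adjusted p = 0.154 with an estimated correlation). TGF-beta and BMP genes had 0 of 19 over all genes and 10 higher adjusted over the list alone, with Tgfb1 at 0.66 ± 0.12 (camera adjusted p = 1.02e-07, adjusted p = 0.203 with an estimated correlation). Fibroblast markers had 0 of 14 over all genes and 10 higher adjusted over the list alone, with a mean of 0.73, or 0.475 without wild type TAC replicate 3 (camera adjusted p = 5.9e-09, adjusted p = 0.212 with an estimated correlation). Fatty acid oxidation genes had 0 of 21 over all genes and 14 lower adjusted over the list alone, with a mean of -0.34 and Hadh at -0.50 ± 0.10 (camera adjusted p = 2.05e-10, adjusted p = 0.209 with an estimated correlation).

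By limma 3 genes passed in this comparison, all higher, while 695 had an adjusted p under 0.1 and 3928 an unadjusted p under 0.05. Groups did not overlap for 19.2% of genes, where chance gives 10%. The count was 774 without wild type TAC replicate 2, 152 without knockout TAC replicate 3 and between 0 and 1 without any other array. It was 530 without dim genes, 30 with a trended and robust variance, 1 after quantile normalization, centring or with the array median as a covariate, and 0 with all probe sets tested, with Myl7 as a covariate or with only the 6 TAC arrays. Col1a1 stood at 11.10, 12.40 and 10.07 in wild type TAC replicates 1 to 3 and at 12.99 to 13.51 in the knockout TAC hearts.

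**Figure D3:**
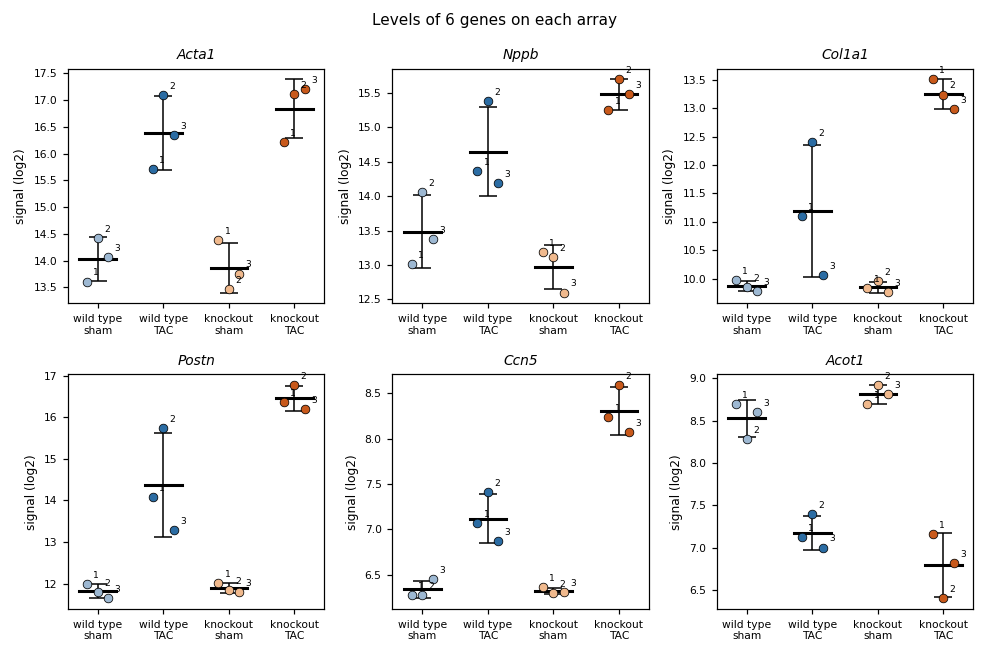
Signal (y axes, log2) of Acta1, Nppb, Col1a1, Postn, Ccn5 and Acot1 on each array by group (x axes), with the mean (line), SD (bar) and replicate number. Postn stands at 14.37 in wild type TAC and 16.45 in knockout TAC hearts, while Acta1 stands at 16.38 and 16.84.

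The interaction asked gene by gene whether the TAC response differed between genotypes, and 0 genes passed by limma, with the smallest adjusted p at 0.259. The genes with the smallest p were Fam180a (0.97 ± 0.13), Txnip (2.38 ± 0.38), Rpl26-ps2, Ccn5 (1.20 ± 0.21) and Nmrk2 (1.27 ± 0.22) upward and Rtn4r, Prxl2a, Irx4, Fn3k and Gabrr2 (-0.81 to -0.63) downward. Collagen and matrix genes had a mean interaction of 1.62, with 0 of 31 over all genes and 25 higher adjusted over the list alone (camera adjusted p = 2.5e-27, adjusted p = 0.304 with an estimated correlation). Fatty acid oxidation genes had a mean of -0.33, with 0 of 21 over all genes and 10 lower adjusted over the list alone (camera adjusted p = 5.6e-08, adjusted p = 0.304 with an estimated correlation). At an unadjusted p under 0.05 there were 2962 genes against 1349 expected by chance, and 151 genes passed without wild type TAC replicate 2.

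After sham surgery the genotypes differed little. Txnip differed by -2.03 ± 0.27 (adjusted p = 0.21), lower in the knockout, at 15.17 ± 0.43 against 17.20 ± 0.41 (SD, n = 3). Its fall after TAC in wild type hearts and its interaction used the same wild type sham arrays. Fnip2 differed by 0.67 ± 0.10 and Ighv5-6 by 0.90 ± 0.14, both at adjusted p = 0.21. Csdc2, Lrrc52 and Get3 upward and Rbm8a2, Dpy19l4, Klf11 and Srp54c downward had larger adjusted p. Unfolded protein response genes had a mean of -0.20, or -0.13 and no call without wild type sham replicate 1, with 0 of 16 over all genes and 0 adjusted over the list alone, Hspa5 at -0.38 ± 0.15 and Dnajb9 at -0.68 ± 0.22 (camera adjusted p = 0.012, adjusted p = 0.992 with an estimated correlation). Genes of glucose uptake and glycolysis had a mean of 0.07, with 0 of 18 over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.992 with an estimated correlation). By limma 0 genes passed, 1493 had an unadjusted p under 0.05 against 1349 expected by chance, and 12.3% did not overlap, where chance gives 10%. Across genes, the genotype differences after sham and after TAC, which share no arrays, had r = -0.04.

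Averaged over surgery, 0 genes differed between genotypes by limma, with the smallest adjusted p at 0.258 and 2739 genes at an unadjusted p under 0.05. Adam15, a relative of Adam12, differed by 0.28 ± 0.05, higher in the knockout, but did not pass. Its groups did not overlap after either surgery, which held for 2.6% of all genes. Plvap, Mmp3, Anxa2 and Ccn5 were next upward, while Dpy19l4, Lmod3, Cth, Lsmem1 and Prrg1 led downward. Collagen and matrix genes had a mean of 0.82, the average of 0.01 after sham and 1.63 after TAC, with 0 of 31 over all genes and 28 higher adjusted over the list alone (camera adjusted p = 4.25e-28, adjusted p = 0.223 with an estimated correlation). Without wild type TAC replicate 2 the count was 141.

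**Figure D4:**
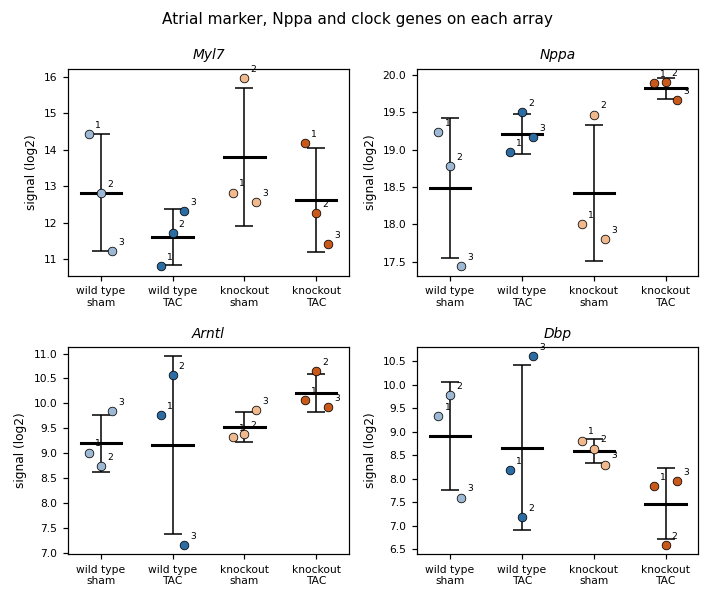
Signal (y axes, log2) of Myl7, Nppa, Arntl and Dbp on each array by group (x axes), with the mean (line), SD (bar) and replicate number. Arntl lies at 7.16 and Dbp at 10.6 in wild type TAC replicate 3, while Myl7 spans 5.16 over the 12 arrays.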

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

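The tests of a lower share of heart muscle cells and of load as a single factor were chosen only after the result was seen, as was the array median as a covariate.

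The TAC response was larger in knockout than in wild type hearts on the score, by 0.592, and the responses of 14 lists differed between genotypes by camera at its preset correlation. The mean interactions were 1.618 for collagens and matrix, 0.744 for fibroblast markers, 0.651 for matrix proteases, 0.614 for TGF-beta and BMP signalling (median 0.363), 0.548 for fetal and hypertrophy genes, 0.525 for proliferation and 0.485 for macrophage and monocyte markers. They were 0.353 for the interferon response, 0.309 for the unfolded protein response (-0.22 in wild type and 0.09 in knockout hearts after TAC, the latter -0.035 without knockout TAC replicate 1 and 0.177 without replicate 3), 0.302 for integrins, 0.284 for the IGF axis and 0.154 for the ADAM family, and they were -0.327 for fatty acid oxidation and -0.277 for oxidative phosphorylation. The TGF-beta and BMP mean holds Bmp10, which is also an atrial marker and had an interaction of 3.98 ± 4.01. Bmp10 was chosen here after its values were seen. Without wild type TAC replicate 3 the interactions were 0.114 for the interferon response, 0.174 for the IGF axis and 0.494 for fibroblast markers. Without knockout TAC replicate 1 that of the unfolded protein response was 0.185, and without knockout TAC replicate 2 that of macrophage and monocyte markers was 0.321. With an estimated correlation 0 of the 34 lists passed, the smallest adjusted p being 0.304, 0 passed by fry, and 22 of 100 splits of the samples called as many lists as the 14 called here, up to 19, so chance is not excluded for that count. Gene by gene 0 passed, a count that each of the 100 splits reaches by construction and that says nothing about chance, and the highest other split called 2.

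For the larger response, technical and procedural explanations were weighed against genotype. The score is a difference between means of the same array, so a constant offset of an array cancels in it. Centring (0.62) therefore could not test array level. The score's interaction was 0.574 after renewed quantile normalization and 0.548 with the array median as a covariate. Without them it was 0.592 ± 0.158 (SE from the spread of arrays within groups). These values argue only against differences that those steps remove. Other effects of the authors' normalization were not tested. A lower share of heart muscle cells was tested only in the form in which markers of all other cells rise alike. After TAC endothelial markers were higher in the knockout by 0.024 and fibroblast markers by 0.725 (0.475 without wild type TAC replicate 3), a difference of 0.701. Its SE of 0.203 was taken over the lists' genes, which move together, so it does not measure the spread between hearts. Relative to wild type sham, fibroblast means were 0.542, 0.998 and 0.019 on wild type and 1.017 to 1.45 on knockout TAC arrays. Endothelial means were 0.338, -0.042 and -0.066 on wild type and 0.06 to 0.156 on knockout TAC arrays. The endothelial difference between genotypes was 0.155 without wild type TAC replicate 1, -0.035 without replicate 2, -0.047 without replicate 3, -0.003 without knockout TAC replicate 2 and 0.045 without replicate 3. The fibroblast minus endothelial difference was 0.522 to 0.999 without single TAC arrays, at least 2.78 times its SE over genes. A rise of all other cells alike is thus argued against over these genes only, not over hearts. A lower muscle share through a rise of some other cells alone was not tested, and a change in fibroblasts themselves stays open. A stronger pressure load in the knockout hearts could give the same picture, and it cannot be told apart from genotype, because the files held no gradient: the ratios of knockout to wild type response were 2.50 for the matrix list and 1.66 for fatty acid oxidation, a difference of 0.838 with a jackknife standard error of 1.345. An effect of the missing gene itself stays open as untested.

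Comparisons of 3 arrays against 3 allow 10 splits, too few for a share under 0.05. TAC called 48 genes in wild type and 3444 in knockout hearts, and 0 in the highest other split of each. It called 17 lists in each genotype, with 14 and 16 in the highest other splits. Genotype called 3 genes after TAC, with 1 in the highest other split, and 0 after sham, a count that all 10 splits reach by construction. It called 15 lists after TAC, with 15 in the highest other split, so that 2 of 10 splits reached the real count, and 2 lists after sham, where 8 of 10 splits reached it and the highest called 10. Averaged over genotypes, TAC called 3673 genes, reached by 1 of 100 splits, the real one. That share is the lowest that 100 splits allow and lies under 0.05, so chance is argued against but not excluded. The highest other split called 2154 and kept all knockout arrays in place. The 15 lists of that comparison were reached by 11 of 100 splits, with up to 18, and the 16 lists of genotype averaged over surgery by 11 of 100, with up to 18, so chance is not excluded for either. Genotype averaged over surgery called 0 genes, which all 100 splits reach by construction, and the highest other split called 1.

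Probe sets outside the genes tested also passed: 32 without a gene symbol here in wild type hearts after TAC and 1078 in knockout hearts, in a fit of all probe sets. Probe sets with several symbols passed in 191 cases in knockout hearts after TAC.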

How the results depend on the processing

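The array median and Myl7 as covariates were the tests chosen only after the result was seen; the cause of the changes below was not tested unless named. For TAC in the wild type, the 48 genes became 0 to 264 without single arrays, 266 with the replicate number as a block, 74 (39 higher and 35 lower) after quantile normalization, 167 without dim genes (fewer genes tested), 352 with array weights, 0 with Myl7 and 0 with only the groups compared (fewer samples). Arrays share only a replicate number: the deviations of the 18 same-number pairs correlated at -0.07 to 0.31 (10 over 0.1), with a mean of 0.116 against -0.058 for different numbers, and 8 of 12 arrays correlated best with their own number. For TAC in the knockout, single arrays gave 2098 to 3688 genes and a fold of at least 1.5 gave 1518, and for TAC averaged over genotypes that fold gave 818. For genotype after sham, single arrays gave 0 to 1 genes and 0 to 4 lists, array weights 1 list and the array median 1 list. For genotype after TAC, the 3 genes became 0 to 774 without single arrays, 593 with the block, 1 after quantile normalization, 1 after centring, 530 without dim genes, 0 among all probe sets, 30 with a trended and robust variance, 1 with the array median, 0 with Myl7 and 0 with only the groups compared. For the interaction single arrays gave 0 to 151 genes, and for genotype averaged over surgery 0 to 141, with 1 gene under the block. The list counts fell to 0 in all 7 comparisons with an estimated correlation. By fry they fell to 0 for TAC in the wild type, genotype after sham, the interaction and genotype averaged over surgery. They fell to 8 for genotype after TAC by fry, while it called 17 lists for TAC in the knockout and 21 for TAC averaged over genotypes. The score's interaction was 0.466 to 0.794 without single arrays and 0.643 (exact permutation p = 0.05) with all probe sets tested. Signs turned for atrial markers in the wild type with Myl7 (0.128, from -0.65) and for genes that had not passed: Myh6 (0.049) and Atp2a2 (0.002) there after quantile normalization, Myh6 after TAC between genotypes after centring (0.012) and averaged over genotypes after quantile normalization (0.002). Between genotypes after TAC, unfolded protein response genes ranged from -0.014 (without knockout TAC replicate 1) to 0.198 and Pdk4 from -0.083 (without knockout TAC replicate 2) to 0.646. The mean of TGF-beta and BMP genes between genotypes averaged over surgery turned to -0.089 with array weights, -0.001 with the array median, -0.128 with Myl7 and without single arrays ranged from -0.063 to 0.102, negative without wild type sham replicate 3, wild type TAC replicate 1, knockout sham replicate 2 or knockout TAC replicate 1. Over all results, single genes and lists included, direction and side of the threshold were kept in 391 of 440 values with Myl7, 416 with all probe sets, 416 with the array median, 423 with the block, 426 with array weights, 427 after centring, 431 after quantile normalization, 436 with a trended and robust variance and 438 with the mean of a gene's probe sets, in 411 of 436 without dim genes, 216 of 247 with only the groups compared and 4785 of 5280 without single arrays, and for lists in 38 of 96 by fry and 0 of 96 with an estimated correlation. Signal over background limits dim genes: background probe sets had medians of 2.96 to 3.17, and Adam12 lay near 4.5.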

Other observations

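The tests of clock genes, of unequal atrial tissue, with Myl7 as a covariate and of genes chosen here for fibroblast state were chosen only after the result was seen.

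Beyond the groups described above, TAC in knockout hearts raised 4 of 16 immediate early genes, Myc by 0.78 ± 0.14 and Ccn1 by 1.18 ± 0.32 among them (camera adjusted p = 0.00177, adjusted p = 0.309 with an estimated correlation), and as many adjusted over the list alone. Of 8 adipocyte markers the lipase genes Pnpla2 (-1.68 ± 0.21) and Lipe (-0.53 ± 0.15) fell, both of which heart muscle also expresses, and as many adjusted over the list alone (camera adjusted p = 0.047, adjusted p = 0.334 with an estimated correlation). Of 8 fibroblast genes chosen after their values were seen, Col1a1 rose by 3.40 ± 0.42, Meox1 by 3.23 ± 0.42, Mfap5 by 3.18 ± 0.36, Cthrc1 by 1.51 ± 0.27 and Tcf21, a factor of resting fibroblasts, by 0.45 ± 0.12, while Dcn (0.47 ± 0.16), Gsn (-0.37 ± 0.18) and Dpep1 (-0.26 ± 0.18) did not pass, and no difference between these genes was tested. Growth and signalling lists held genes that moved both ways: in the MAPK, calcineurin and G protein list 5 of 34 rose and 10 fell (Ace 1.94 ± 0.23, Adra1b -0.70 ± 0.10), and in the PI3K, AKT and mTOR list 3 of 24 rose and 5 fell. In the EGF family list 2 of 11 rose (Ereg and Egfr) and 2 fell (Erbb4 and Egf), and in glucose uptake and glycolysis 1 of 18 rose and 5 fell.

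Markers of further cells were not called as lists in knockout hearts after TAC, though single members passed by limma. Csf3r among neutrophil markers, Ighm among B cell markers and 1 Schwann cell and neuron marker rose. Among smooth muscle and pericyte markers Cspg4 rose and Abcc9 fell. Camera called none of the 8 lists for neutrophils, T and NK cells, B cells, smooth muscle cells and pericytes, erythroid cells, skeletal muscle, Schwann cells and neurons, and mesothelium, with means from -0.09 for erythroid cells to 0.23 for smooth muscle cells and pericytes. Single arrays moved 7 of these means, all but the erythroid one, by over 1.5 times: smooth muscle cells and pericytes had 0.102 without knockout sham replicate 3, neutrophils -0.007 without knockout TAC replicate 2 (from 0.12), B cells 0.033 without that array (from 0.08) and mesothelium -0.01 without knockout sham replicate 1 (from 0.15). The circadian clock list had a mean of -0.27, or -0.158 without knockout TAC replicate 2, with 0 of 16 past the threshold by limma. In the atrial list 1 of 10 was lower (Tbx5), and the sign of its mean of -0.24 rested on single arrays, with 0.405 without knockout sham replicate 2 and 0.241 without knockout TAC replicate 3. Of 30 neighbours of Adam12, 4 rose after TAC in knockout hearts (Mki67, Cpxm2, Chst15 and Dock1) and 4 fell (Acadsb, Oat, Ikzf5 and Uros). As many passed adjusted over the list alone. Those beyond the 4 with the smallest p were chosen after their values were seen. Camera called the list neither there nor between genotypes after sham, where 0 of 30 passed by limma. Sex-linked genes had a mean of -0.24 (camera adjusted p = 0.047, adjusted p = 0.314 with an estimated correlation), where 1 of 6 fell, Tsix.

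Clock genes deviated most on wild type TAC replicate 3. There Arntl differed by -3.01 and Dbp by 2.91 from the mean of the other wild type TAC arrays, and the mean absolute deviation of 16 clock genes was 1.264, against 0.964 on wild type TAC replicate 2, 0.574 on wild type sham replicate 3, 0.530 on knockout TAC replicate 2 and 0.125 to 0.408 on the other 8 arrays. Each array was compared with the mean of the other arrays of its group. The values of wild type TAC replicates 1 and 2 therefore also hold the deviation of replicate 3. On wild type TAC replicate 3, 10000 random lists of other genes of like signal deviated by a median of 0.201 and by 0.498 at the highest. Those lists held unlinked genes, so they cannot show whether a loss of quality moved linked genes together. A general loss of quality as the source of the clock deviation is therefore not decided. The collagen and matrix list and the atrial list deviated by 1.283 and 1.275 on that array, about as much as the clock genes. Fibroblast markers (0.751), interferon response (0.717), TGF-beta and BMP (0.703), matrix protease (0.681) and mesothelial genes (0.545) also lay above 0.498. Some loss of quality beside the clock deviation stays open, since all other genes also deviated most on it, by a median of 0.153 against 0.141 at the highest and 0.107 at the median of the other 11 arrays. Another phase of the daily cycle at collection is a candidate explanation for the clock genes: 13 of 13 measured genes with a known side moved as a shift of phase would move them. The files gave no time of collection.

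Atrial markers varied between arrays, also within groups. Myl7 ranged from 10.81 to 12.33 in wild type TAC hearts, the narrowest group, and from 12.58 to 15.97 in knockout sham hearts, the widest. Sln spanned 5.40, Myl7 5.16 and Bmp10 10.71 over the 12 arrays, and the deviations of atrial markers from their group means had a median pairwise r of 0.821 over 45 pairs. Unequal amounts of atrial tissue in the samples may account for this. It is argued against as the source of the difference of Nppa between TAC and sham: with Myl7 as a covariate the averaged difference was 1.521 ± 0.203 (adjusted p = 0.00177), against 1.061 ± 0.328 (adjusted p = 0.0551) without it. Knockout and wild type TAC hearts then differed by 0.21 in Nppa, against 0.60 ± 0.46 (adjusted p = 0.592 by limma) without Myl7. Atrial tissue is therefore not argued against for this difference between genotypes. The knockout TAC values of Nppa lie near the top of the table and may be compressed.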
